A study of Saccharomyces cerevisiae with 36 samples.

How the data were processed

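Per the labels, budding yeast cultures were treated with calcofluor white (0.02 or 0.1 mg/ml), congo red (0.02 or 0.1 mg/ml) or caffeine (2 or 20 mM) for 5, 15 or 90 min, and treated and untreated RNA were hybridised together on 2-colour arrays. The design text of the series states 2 biological replicates in a dye swap, so the 36 arrays form 18 conditions of 2 arrays, with treated RNA in Cy5 in replicate 1 and in Cy3 in replicate 2. Dye orientation and replicate number are therefore the same factor. On 7 arrays a part of the labels disagrees with the rest. The description gives another dose for calcofluor white 0.02 mg/ml 5 min replicate 1 and congo red 0.02 mg/ml 90 min replicate 1, another time for calcofluor white 0.1 mg/ml 15 min replicate 1, and another dose and time for calcofluor white 0.02 mg/ml 15 min replicate 1. One channel gives another time for caffeine 20 mM 15 min replicate 1 and calcofluor white 0.02 mg/ml 15 min replicate 2, and another dose for calcofluor white 0.1 mg/ml 15 min replicate 2. The title was followed in each case.

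The deposited values are natural log (ln) ratios, with a mean of 0 over the spots of each array, as read from the values themselves. They were taken as treated over untreated RNA, as described below. The scanner, background correction and normalization method are not given in the sources used here. Of 15488 spots, 11872 carry a gene name and 3616 do not, and the named spots cover 5713 genes, of which 5670 have 2 spots, 31 have 4 and 12 have 34. Each array holds a repeated value for spots at a floor, 1.609% to 16.09% of the named spots (median 5.42%), and these were treated as missing. A further 20 to 72 values per array were each shared by at least 10 spots and were kept. Of these, 94.12% to 100% stood to the floor ratio as small whole numbers, so spots close to the floor may remain. Values were divided by 0.6931 to give log2, averaged over the spots of a gene and centred on the array median.

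Whether the 2 dye orientations carry the same sign was read from their correlation. It was 0.672 for caffeine 20 mM at 90 min and 0.531 at 15 min, so there both orientations run the same way. A common sign cannot tell treated over untreated from its inverse, and treated over untreated was assumed throughout. In the other conditions the correlation lay between −0.524 and 0.148, since dye effects of genes run opposite ways in the 2 orientations. Among 306 pairs of arrays of 1 orientation, the lowest correlation was −0.375, between caffeine 2 mM 15 min and 5 min replicate 1, and a fit with the sign of the latter turned was run as an alternative.

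Genes with a value on at least 24 of 36 arrays and on both arrays of each condition compared were tested, 5391 genes having enough arrays. Limma 3.58.1 in R 4.3.3 was fitted to all arrays with 18 condition terms and a dye term per gene, which is also the replicate block, with 17 residual degrees of freedom, a prior of 3.187 degrees of freedom and a median residual SD of 0.2439. The block was kept because the deviations of arrays with the same replicate number from their condition means correlated above 0.1 in 153 of 153 pairs of conditions (0.114 to 0.826, median 0.58). The dye term passed the threshold for 2829 of the 4242 genes measured on all arrays. P values were adjusted by Benjamini-Hochberg within a comparison, at 0.05. The number of arrays limits the precision, and the median standard error of a condition was 0.163. Values were prepared with python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

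Named genes followed a rule. For each drug they were the 10 highest and 10 lowest genes past the threshold at any time of the higher dose, with the same sign on both arrays, at the time of their largest change. For dose, time and drug contrasts they were the 5 highest and 5 lowest past the threshold, or where none passed the 5 with the smallest p. For each gene list they were up to 4 members with the smallest p. The comparisons, the rule, 38 gene lists and the other settings to try were fixed before the data were examined. Some lists share members, so their calls are not all separate. The lists were tested in the 9 conditions of the higher doses with camera at a preset correlation of 0.01 and at least 4 members, over 5238 genes with missing values filled from the fit, which gives 342 tests adjusted together. Each was repeated with an estimated correlation and with fry.

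The procedure was tested on simulated data with 100 genes changed by a log2 of 1 and 100 by 2. Of these it recovered 85 and 99 for calcofluor white at 90 min (10 false of 194 calls), 99 and 100 for the mean of low-dose caffeine (7 of 206), 94 and 99 for the doses of caffeine (12 of 205) and 96 and 100 for caffeine against the dyes (12 of 208). The simulated noise was independent between genes and equally wide on all arrays, as the fit assumes. The real arrays differed in their spread across genes (scaled median absolute deviation 0.1993 to 0.7392). The simulation therefore checks the procedure, but not how it does with unequal arrays or correlated genes.

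The other settings were no replicate block, values as deposited without centring, arrays scaled to one spread, genes on all arrays alone, only the arrays of the drugs compared, array weights, a robust prior, one value per spot and leaving out each array. The scaling used limma's normalizeMedianAbsValues in place of normalizeBetweenArrays, which had been named before the data were seen. Chosen after the data were seen were floored spots kept at their value, medians of well rows and columns removed, the turned sign, the contrasts at 90 min alone and the lower doses at single times. Other splits of the samples were limited to genes measured on all arrays and to exchanges within time and dye orientation, or sign changes of the 6 low-dose arrays.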

Results

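Transcript ratios were measured in budding yeast exposed to 3 compounds that disturb the cell wall. Calcofluor white and congo red are dyes that bind wall chitin and glucan, and caffeine is a methylxanthine to which cells with a weakened wall are sensitive. Each drug was given at 2 doses, 0.02 and 0.1 mg/ml for each dye and 2 and 20 mM for caffeine, and cells were taken after 5, 15 and 90 min. The 36 arrays formed 18 conditions of 2 arrays each, with treated RNA in Cy5 in replicate 1 and in Cy3 in replicate 2, and untreated RNA in the other channel. Every condition below therefore has n = 2, and the number of arrays limits the precision. The median standard error of a single condition was 0.163 on the log2 scale. Values are log2 ratios, taken as treated over untreated cells, ± SE from limma. The SE rests on 1 residual variance per gene over all 36 arrays. It therefore does not measure the spread of the 2 arrays of the condition beside which it stands. A gene is said to have changed where its Benjamini-Hochberg adjusted p was below 0.05. The design asked which genes responded to each drug, when, at which dose, and whether the drugs differed.

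After 90 min of calcofluor white at 0.1 mg/ml, the output genes of the cell wall integrity pathway were higher as a list, a call kept with an estimated correlation (adjusted p = 0.0197). The lists of ribosomal proteins and ribosome biogenesis were lower, but both calls were lost with an estimated correlation (adjusted p = 0.136 and 0.272). PIR3 (YKL163W), a mannoprotein linked to wall glucan, rose by 2.65 ± 0.218, a 6.28-fold increase. CWP1 (YKL096W), a GPI-anchored wall mannoprotein, rose by 2.03 ± 0.249. HSP12 (YFL014W), a small membrane-associated stress protein, rose by 2.12 ± 0.177, and NCE103 (YNL036W), a carbonic anhydrase, by 1.96 ± 0.21. HSP150 (YJL159W), a wall protein related to PIR3, rose by 2.01 ± 0.446. CSS3 (2.33 ± 0.285), CPP3 (1.94 ± 0.324), YKE4 (1.74 ± 0.384), the wall protein gene NCW2 (1.69 ± 0.273) and the methyltransferase gene CRG1 (1.68 ± 0.16) completed the 10 highest. The lowest value was that of PHO11 (YAR071W), a secreted acid phosphatase, at −2.66 ± 0.336, with −1.13 and −4.19 on its 2 arrays. PHO3, another acid phosphatase gene, fell by 1.47 ± 0.217 and FAA4, encoding an acyl-CoA synthetase, by 1.27 ± 0.178. Also lower were the genes RSA3 (−1.7 ± 0.335) and ARX1 (−1.49 ± 0.27), both of 60S subunit assembly. The vacuolar zinc transporter gene ZRC1 (−1.53 ± 0.351), the elongin C gene ELC1 (−1.35 ± 0.241), the nucleoporin gene NUP188 (−1.28 ± 0.277), RPA135 of RNA polymerase I (−1.27 ± 0.337) and ARP6 (−1.23 ± 0.355) fell as well. In all, limma called 772 of 5216 genes, 335 higher and 437 lower. The count was 231 without the replicate block, 352 with arrays scaled to one spread, 240 without replicate 2 and 399 without replicate 1. With the values as deposited, not centred, the split was 219 higher and 515 lower. YKE4, ZRC1, ELC1, RPA135 and ARP6 did not pass without the replicate block, YKE4, RPA135 and ARP6 did not pass with scaled arrays, and ARP6 did not pass with only the arrays of this drug. Without replicate 2, HSP150 (1.12), YKE4 (1.96), RSA3 (−0.363), ZRC1 (−1.22), NUP188 (−0.175), RPA135 (−0.783) and ARP6 (0.0182, of opposite sign) did not pass. The same held without replicate 1 for YKE4 (1.51), ARX1 (−0.953) and ELC1 (−0.887).

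Of the 21 measured output genes of the cell wall integrity pathway, 16 rose at this condition, 0 fell and 5 did not pass, and adjusted over the list alone the numbers were 16 and 0. The list median was 0.942 (camera adjusted p = 6.49e-13, and adjusted p = 0.0197 with an estimated correlation). PST1, a GPI-anchored wall protein gene, rose by 0.834 ± 0.119 and the yapsin protease gene YPS3 by 0.942 ± 0.151. Among 27 genes of wall mannoproteins, 13 rose, 2 fell and 12 did not pass, against 16 higher and 3 lower adjusted over the list alone. Their median was 0.64, with SED1, the major GPI wall protein of stationary cells, at 1.64 ± 0.289 (camera adjusted p = 1.33e-07, and adjusted p = 0.26 with an estimated correlation). Of 122 genes of cytosolic ribosomal proteins, 0 rose, 90 fell and 32 did not pass, and 106 were lower when adjusted over the list alone. Their median was −0.643, with RPL42A at −0.939 ± 0.108, RPS1A at −0.968 ± 0.111, RPS1B at −0.939 ± 0.114 and RPS10A at −0.937 ± 0.117 (camera adjusted p = 4.46e-43, and adjusted p = 0.136 with an estimated correlation). RPL42A and RPS10A did not pass without the replicate block. Of 102 ribosome biogenesis genes, 0 rose, 23 fell and 79 did not pass (26 lower adjusted over the list alone). The median was −0.211, with NOP58, a C/D snoRNP protein gene, at −0.843 ± 0.161 (camera adjusted p = 6.74e-06, and adjusted p = 0.272 with an estimated correlation). NOP58 did not pass without the replicate block.

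Several smaller lists were also called after 90 min of calcofluor white at 0.1 mg/ml, each lost with an estimated correlation. Of 15 phosphate starvation genes, 0 rose, 6 fell and 9 did not pass (1 higher and 10 lower adjusted over the list alone), among them the acid phosphatase gene PHO12 at −1.23 ± 0.233 and the polyphosphate polymerase subunit gene VTC3 at −0.8 ± 0.146 (camera adjusted p = 0.00029, and adjusted p = 0.14 with an estimated correlation). Without replicate 2, PHO12 (−0.671) and VTC3 (−0.314) did not pass. Of 38 general stress genes, 5 rose, 0 fell and 33 did not pass (5 higher adjusted over the list alone), with the trehalase gene NTH1 at 1.13 ± 0.195 (camera adjusted p = 0.00495, and adjusted p = 0.136 with an estimated correlation). Of 13 calcineurin targets, 4 rose, 0 fell and 9 did not pass (4 higher adjusted over the list alone), with the glucan synthesis genes KRE6 at 0.916 ± 0.131 and GSC2 at 1.36 ± 0.242 (camera adjusted p = 0.0305, and adjusted p = 0.48 with an estimated correlation). The list median was only 0.0862. KRE6 is also on the chitin and glucan synthesis list, and GSC2 on the wall integrity output list. GSC2 did not pass without replicate 1 (0.752). The call of this list was lost over genes on all arrays (adjusted p = 0.0708) and without replicate 1 (adjusted p = 0.143). Of 19 genes of RNA polymerases I and III, 0 rose, 6 fell and 13 did not pass (6 lower adjusted over the list alone), with RPA43 at −0.914 ± 0.119 (camera adjusted p = 0.0158, and adjusted p = 0.272 with an estimated correlation).

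At 5 and 15 min of calcofluor white at 0.1 mg/ml few genes could be told from the replicate spread. At 5 min limma called 0 of 5182 genes, 144 had an unadjusted p under 0.05, fitting with array weights called 5, and leaving out replicate 1 or 2 gave 5 or 28. The 5 genes with the smallest p, none of which passed, were ARO80 (−0.727 ± 0.148), XKS1 (−1.01 ± 0.213), RPS23B (−2.33 ± 0.561), LGE1 (−0.78 ± 0.197) and OST3 (1.24 ± 0.313, and −0.107 without replicate 1). At 15 min 1 of 5082 genes passed, MRPL27 of the mitochondrial ribosome, at −1.22 ± 0.194, a gene named after its values were seen. The count was 0 without the replicate block, 30 with scaled arrays (5 higher and 25 lower), 24 with array weights, 25 with well medians removed, 42 over genes measured on all arrays, 0 with only the arrays of this drug, 2 with floored spots kept, 14 without replicate 1 and 115 without replicate 2. At 15 min the wall integrity output list was already higher as a group, with a median of 0.294, although 0 of its 21 genes rose or fell and 21 did not pass, also when adjusted over the list alone (camera adjusted p = 8.96e-09, and adjusted p = 0.0533 with an estimated correlation). PIR3 stood at 0.686 ± 0.219 and NCW2 at 0.748 ± 0.273 at that time, neither past the threshold.

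After 90 min of congo red at 0.1 mg/ml CWP1 and PIR3 stood highest. CWP1 rose by 2.47 ± 0.25, a 5.55-fold increase, PIR3 by 2.46 ± 0.219, and CRG1 by 1.66 ± 0.16. The phospholipid flippase gene DNF2 (YDR093W) rose by 1.58 ± 0.233, SRL3 (YKR091W) by 1.31 ± 0.171 and YNL058C by 1.27 ± 0.144. CSS3 (1.71 ± 0.286), the pH-sensing gene RIM21 (1.63 ± 0.34), YKE4 (1.58 ± 0.386) and SED1 (1.3 ± 0.29) also rose. The lower genes were YOL014W (−1.37 ± 0.336), the kinetochore gene AME1 (−1.24 ± 0.282), the siderophore transporter gene ARN2 (−0.787 ± 0.177), RPC11 of RNA polymerase III (−0.787 ± 0.17), and FCY22 (−0.712 ± 0.132). Among them too were YBL044W (−0.709 ± 0.157), RSC1 of a chromatin remodelling complex (−0.619 ± 0.134), RIM9 (−0.603 ± 0.105) and EFM2 (−0.58 ± 0.129). Limma called 74 of 5380 genes, 60 higher and 14 lower. The count was 16 without the replicate block, 133 with only the arrays of this drug and 27 without replicate 2. CSS3, RIM21, YKE4, SED1 and every lower gene except FCY22 did not pass without the replicate block. YKE4 and YBL044W did not pass with scaled arrays. Neither did AME1, ARN2 and RSC1 with only the arrays of this drug, YOL014W, ARN2 and YBL044W with one value per spot, EFM2 uncentred, and AME1 with floored spots kept (−0.758). Without replicate 1, CSS3 (1.67), RIM21 (1.75), DNF2 (1.32), YKE4 (1.43), SED1 (1.05), YOL014W (−1.38), YBL044W (−0.884) and RIM9 (−0.632) did not pass. Without replicate 2, CSS3 (1.75), RIM21 (1.51), YKE4 (1.73), SED1 (1.56) and all 9 lower genes named here did not pass. AME1 then stood at −0.0257, ARN2 at −0.268, RSC1 at −0.301 and EFM2 at −0.342.

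Of the 21 wall integrity output genes, 10 rose, 0 fell and 11 did not pass after 90 min of congo red at 0.1 mg/ml, and 16 were higher when adjusted over the list alone. The median was 0.752 (camera adjusted p = 3.37e-22, and adjusted p = 0.00395 with an estimated correlation), with PST1 at 1.03 ± 0.12. Of 23 genes of chitin and glucan synthesis, 4 rose, 0 fell and 19 did not pass (9 higher adjusted over the list alone), with a median of 0.253 (camera adjusted p = 3.16e-07, and adjusted p = 0.028 with an estimated correlation). These were FKS1, the catalytic subunit of glucan synthase (0.698 ± 0.108), the mannosyltransferase gene KRE2 (0.703 ± 0.113), SKT5, an activator of chitin synthase III (0.656 ± 0.107), and KRE6 (0.663 ± 0.131). FKS1 and KRE6 did not pass without the replicate block, and KRE2 (0.565), SKT5 (0.604) and KRE6 (0.489) did not pass without replicate 1. Without replicate 1 the call of the list was lost (adjusted p = 0.0559). Of 28 wall mannoprotein genes, 7 rose, 0 fell and 21 did not pass (8 higher adjusted over the list alone), with PIR1 at 1.13 ± 0.233 (camera adjusted p = 2.99e-07, and adjusted p = 0.268 with an estimated correlation). PIR1 did not pass without replicate 1 (1.01) or replicate 2 (1.25). Of the 122 ribosomal protein genes, 0 rose, 0 fell and 122 did not pass, also when adjusted over the list alone, and the list median was −0.192 (camera adjusted p = 3.13e-14, and adjusted p = 0.485 with an estimated correlation). With fry its adjusted p was 0.126.

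At 5 min of congo red at 0.1 mg/ml 1 of 5347 genes passed in limma, SNX3 (YOR357C), a sorting nexin gene, at −0.981 ± 0.166, with −1.94 and −0.0171 on its 2 arrays. SNX3 did not pass without the replicate block, uncentred, with only the arrays of this drug, with floored spots kept, with well medians removed, with one value per spot, or without replicate 1 (−0.353), and the count was 0 under each of those settings except the last, where it was 7. It was also 0 over genes with a value on all arrays, 8 with scaled arrays (3 higher and 5 lower) and 7 without replicate 2. At 15 min limma called 0 of 5355 genes, 45 had an unadjusted p under 0.05, and leaving out replicate 1 or replicate 2 gave 5 or 4. The smallest p values there belonged to SER33 (1.38 ± 0.278), BOR1 (−1.06 ± 0.26, and 0.0303 without replicate 2), LEU4 (−1.05 ± 0.259), PCD1 (−1.2 ± 0.299) and CRT10 (−1.11 ± 0.303), none of which passed. The wall integrity output list had a median of 0.133 at 15 min, with 0 of 21 genes higher or lower and 21 not past the threshold, also when adjusted over the list alone (camera adjusted p = 1.59e-05, and adjusted p = 0.167 with an estimated correlation). That call was lost with fry (adjusted p = 0.287) and without replicate 1 (adjusted p = 0.853).

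**Figure D1:**
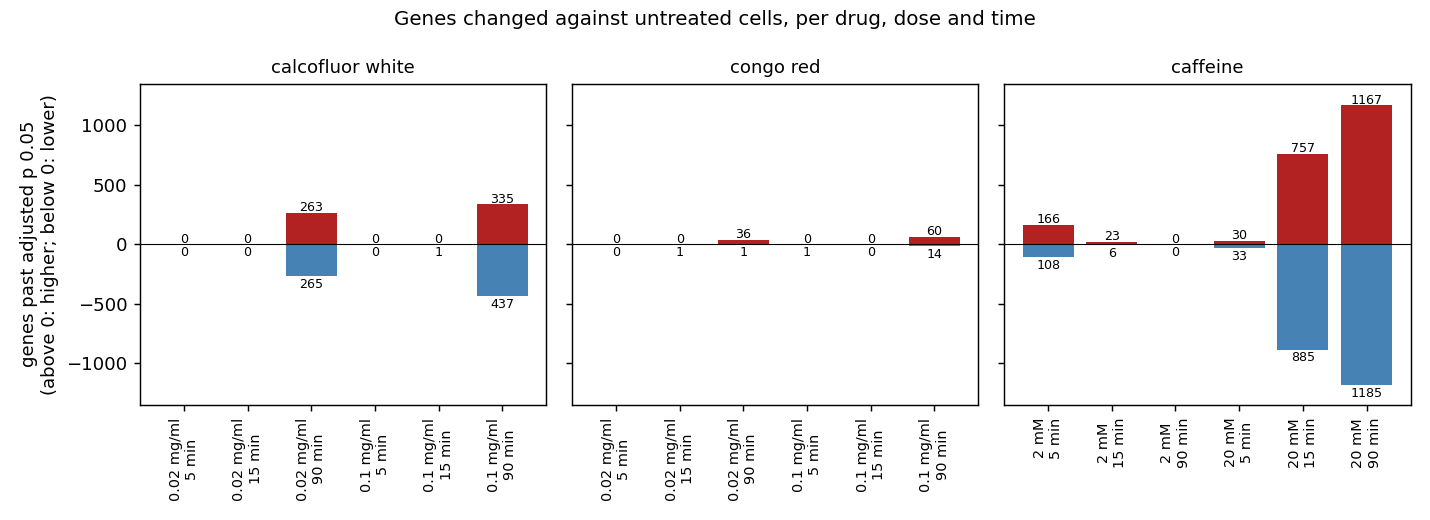
Number of genes past an adjusted p of 0.05 (y axis, higher genes above 0 and lower genes below 0) for each drug, dose and time (x axis), from 2 arrays per condition. Both dyes have their highest counts at 90 min, and caffeine at 20 mM goes from 30 higher and 33 lower genes at 5 min to 1167 higher and 1185 lower at 90 min.

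The 2 wall-binding dyes, given at matched doses of 0.1 mg/ml, were compared directly. Averaged over the 3 times, limma called 0 genes, with 464 at an unadjusted p under 0.05, and leaving out calcofluor white 15 min replicate 2 gave 73. The smallest p values belonged to DET1 (congo red minus calcofluor white 0.393 ± 0.0847), DAS2 (0.388 ± 0.0845), VEL1 (0.377 ± 0.0815), RPL42A (0.395 ± 0.0877) and RCR1 (−0.696 ± 0.155), each with an adjusted p = 0.192. Counts without 1 other array were 7 and 11 (calcofluor white 15 min and 90 min replicate 1), 6 and 1 (congo red 90 min replicates 1 and 2), 1 and 3 (congo red 5 min replicates 1 and 2), 3 (congo red 15 min replicate 2) and 1 (calcofluor white 5 min replicate 2). At 90 min alone, a time chosen after the data were seen, 15 genes differed, 7 higher and 8 lower with congo red, but 0 did without the replicate block and 0 with scaled arrays. That count was 24 uncentred (20 higher and 4 lower), 47 with only the arrays of these drugs, 8 with array weights, 5 with floored spots kept and 9 with well medians removed. It was 54 and 4 without congo red replicate 1 and 2, and 52 and 5 without calcofluor white replicate 1 and 2. Of the 35 genes named for either dye, 2 passed at 90 min: HSP12 was higher with calcofluor white (difference −1.33, 95% interval −1.86 to −0.813) and RIM9 lower with congo red (−0.99, −1.3 to −0.682). For PIR3 the difference was −0.195 (−0.837 to 0.448), for CWP1 0.441 (−0.29 to 1.17), for CRG1 −0.0202 (−0.49 to 0.45) and for PHO11 1.82 (0.831 to 2.81), and a p that misses the threshold does not show that the dyes act alike. Among genes tested in both, 52 were higher at 90 min with each dye, of 334 with calcofluor white and 60 with congo red, where independent lists would share 3.85. A further 8 were lower with each, where independent lists would share 1.17. The labels do not say whether untreated cultures were shared between drugs, so part of that excess may come from shared controls.

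After 5 min of caffeine at 20 mM a small set of genes had already changed in the fit to all arrays. CIT2, the peroxisomal citrate synthase of the retrograde response, rose by 1.31 ± 0.197, and DIP5, a dicarboxylic amino acid permease, by 1.3 ± 0.195. TYE7, a regulator of glycolytic genes, fell by 1.58 ± 0.176, and SUI1, encoding translation initiation factor eIF1, by 1.16 ± 0.156. CIT2, DIP5, TYE7 and SUI1 were named in other comparisons, not by their rank at this time. None of them passed with only the caffeine arrays, where the count was 0. Of 12 hexose transporter genes, 3 rose, 0 fell and 9 did not pass (5 higher adjusted over the list alone), namely HXT13 (0.848 ± 0.141), HXT7 (0.987 ± 0.176) and HXT6 (0.771 ± 0.175), for a list median of 0.231 (camera adjusted p = 4.76e-05, and adjusted p = 0.0533 with an estimated correlation). HXT6 and HXT7 are near-identical, and other members of the family are close copies, so their separate values are uncertain. HXT6 and HXT7 did not pass without the replicate block, and none of the 3 passed with only the caffeine arrays or without replicate 1 (HXT13 0.769, HXT7 0.965, HXT6 0.772). HXT7 (1.01) and HXT6 (0.77) did not pass without replicate 2 either. Of the 122 ribosomal protein genes, 0 rose, 0 fell and 122 did not pass, also when adjusted over the list alone, with a median of −0.224 (camera adjusted p = 8.46e-13, and adjusted p = 0.514 with an estimated correlation). Fry did not call the list (adjusted p = 0.0947). Limma called 63 of 5260 genes, 30 higher and 33 lower. The count was 5 without the replicate block, 190 with scaled arrays, 0 with only the caffeine arrays, 563 with array weights and 24 without replicate 1.

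After 15 min of caffeine at 20 mM the lists of hexose transporters, nitrogen catabolite repression and general stress were higher, calls kept with an estimated correlation. The lists of ribosomal proteins, ribosome biogenesis and RNA polymerases I and III were lower, but these calls were lost with an estimated correlation (adjusted p = 0.268, 0.514 and 0.272). The lowest gene was NOG2 (YNR053C), a GTPase of 60S subunit export, at −4.06 ± 0.161, a ratio of 0.0601. FCF2 (YLR051C), needed for 18S rRNA processing, fell by 2.92 ± 0.321, SUI1 by 2.4 ± 0.156 and the importin gene NMD5 by 2.25 ± 0.278. Of 13 hexose transporter genes, 10 rose, 0 fell and 3 did not pass (11 higher adjusted over the list alone). The median was 0.83 (0.532 with scaled arrays), with HXT13 at 2.13 ± 0.141, HXT7 at 1.91 ± 0.176 and HXT2 at 1.14 ± 0.128 (camera adjusted p = 7.68e-08, and adjusted p = 0.0197 with an estimated correlation). Of 27 genes under nitrogen catabolite repression, 14 rose, 1 fell and 12 did not pass (16 higher and 1 lower adjusted over the list alone). The median was 0.539, with the ammonium permease gene MEP2 at 3.41 ± 0.329, the glutamate dehydrogenase gene GDH2 at 2.03 ± 0.164 and the activator gene GAT1 at 1.35 ± 0.144 (camera adjusted p = 7.57e-06, and adjusted p = 0.0266 with an estimated correlation). Of 39 general stress genes, 19 rose, 1 fell and 19 did not pass (22 higher and 2 lower adjusted over the list alone), with the hexokinase gene HXK1 at 1.82 ± 0.172 and the glycogen phosphorylase gene GPH1 at 1.22 ± 0.116 (camera adjusted p = 4.04e-06, and adjusted p = 0.0197 with an estimated correlation).

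In the same samples, 92 of 122 ribosomal protein genes fell, 0 rose and 30 did not pass (96 lower adjusted over the list alone). The median was −0.657, with RPS9A at −1.27 ± 0.134 (camera adjusted p = 2.23e-27, and adjusted p = 0.268 with an estimated correlation). Of 105 ribosome biogenesis genes, 5 rose, 37 fell and 63 did not pass (5 higher and 39 lower adjusted over the list alone), with NOC2 at −1.34 ± 0.178 (camera adjusted p = 0.00366, and adjusted p = 0.514 with an estimated correlation). Of 19 genes of RNA polymerases I and III, 2 rose, 10 fell and 7 did not pass (2 higher and 11 lower adjusted over the list alone), with RPA49 at −1.15 ± 0.127 (camera adjusted p = 0.0147, and adjusted p = 0.272 with an estimated correlation). Of 45 genes of the TCA cycle and oxidative phosphorylation, 14 rose, 4 fell and 27 did not pass (15 higher and 5 lower adjusted over the list alone), with the citrate synthase gene CIT1 at 2.13 ± 0.174 and the cytochrome c1 gene CYT1 at 2.53 ± 0.295 (camera adjusted p = 0.0232, and adjusted p = 0.272 with an estimated correlation). Of 14 genes of glycolysis and ethanol formation, 0 rose, 8 fell and 6 did not pass (8 lower adjusted over the list alone), with the pyruvate kinase gene CDC19 at −0.742 ± 0.128 (camera adjusted p = 0.0422, and adjusted p = 0.546 with an estimated correlation). CDC19 did not pass without the replicate block. Without replicate 1 the calls of the polymerase, TCA cycle and glycolysis lists were lost (adjusted p = 0.0877, 0.248 and 0.167). The first 2 were also lost over genes on all arrays (adjusted p = 0.0845 and 0.0559), and glycolysis without the replicate block (adjusted p = 0.331). Limma called 1642 of 5258 genes at 15 min, 757 higher and 885 lower. The count was 667 without the replicate block, 561 with scaled arrays, 797 with only the caffeine arrays and 412 without replicate 1.

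After 90 min of caffeine at 20 mM the largest increases were those of TFS1, APE1 and MEP2. TFS1 (YLR178C), an inhibitor of carboxypeptidase Y, rose by 4.25 ± 0.462, a 19-fold increase. The vacuolar aminopeptidase gene APE1 (YKL103C) rose by 4.23 ± 0.403 and MEP2 (YNL142W) by 4.12 ± 0.329. The allantoin pathway genes DAL3 (3.53 ± 0.27) and DAL5 (3.37 ± 0.407), the aromatic aminotransferase gene ARO9 (3.42 ± 0.236) and the decarboxylase gene ARO10 (3.62 ± 0.128) rose with them. So did the transaldolase paralog NQM1 (3.78 ± 0.444), HSP12 (3.58 ± 0.177) and RRI2 (3.35 ± 0.369). Among the lowest were RPA135 (−2.9 ± 0.337), the U3 snoRNP gene NAN1 (−2.67 ± 0.314), and the helicase gene DBP2 (−2.57 ± 0.381). The 60S assembly genes NOG1 (−2.56 ± 0.327) and NIP7 (−2.47 ± 0.132) fell too, as did RPO31, the largest subunit of RNA polymerase III (−2.29 ± 0.22). Limma called 2352 of 5270 genes, 1167 higher and 1185 lower. The count was 1389 without the replicate block, 899 with scaled arrays, 1541 with array weights and 1187 without replicate 2. Left uncentred, the median gene stood at −0.1192, so changes are relative to that shift.

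Of the 122 ribosomal protein genes, 115 fell, 0 rose and 7 did not pass after 90 min of caffeine at 20 mM (115 lower adjusted over the list alone). The median was −0.977, and −0.485 with scaled arrays, with RPL26B at −1.47 ± 0.101 (camera adjusted p = 2.5e-34, and adjusted p = 0.179 with an estimated correlation). Of 105 ribosome biogenesis genes, 1 rose, 58 fell and 46 did not pass (1 higher and 60 lower adjusted over the list alone). The median was −0.499, and −0.252 with scaled arrays, with NOP58 at −1.89 ± 0.161 (camera adjusted p = 7.36e-10, and adjusted p = 0.136 with an estimated correlation). Of 19 genes of RNA polymerases I and III, 2 rose, 9 fell and 8 did not pass (2 higher and 10 lower adjusted over the list alone), with RPA43 at −2.08 ± 0.119 (camera adjusted p = 0.00938, and adjusted p = 0.268 with an estimated correlation). Of 40 general stress genes, 20 rose, 2 fell and 18 did not pass (22 higher and 2 lower adjusted over the list alone), with NTH1 at 2.37 ± 0.195 and the disaggregase gene HSP104 at 1.33 ± 0.159 (camera adjusted p = 0.000101, and adjusted p = 0.0397 with an estimated correlation). Of 27 genes under nitrogen catabolite repression, 13 rose, 2 fell and 12 did not pass (13 higher and 2 lower adjusted over the list alone), with GDH2 at 2.41 ± 0.164 (camera adjusted p = 0.00366, and adjusted p = 0.136 with an estimated correlation). Wall integrity output genes were also higher, 9 of 21 rising, 1 falling and 11 not past the threshold (9 higher and 1 lower adjusted over the list alone), with SRL3 at 2.09 ± 0.171, PIR3 at 1.79 ± 0.219 and GSC2 at 1.95 ± 0.242 (camera adjusted p = 0.0232, and adjusted p = 0.514 with an estimated correlation). Of 13 calcineurin targets, 7 rose, 0 fell and 6 did not pass (7 higher and 1 lower adjusted over the list alone), with the vacuolar calcium pump gene PMC1 at 1.89 ± 0.21 (camera adjusted p = 0.0118, and adjusted p = 0.38 with an estimated correlation). The nitrogen call was lost over genes on all arrays (adjusted p = 0.0788), the wall integrity call without replicate 1 (adjusted p = 0.208) and the calcineurin call without replicate 2 (adjusted p = 0.0844). With scaled arrays the medians of these 3 lists went from 0.32 to 0.176, from 0.405 to 0.225 and from 0.53 to 0.243. Those of the stress and polymerase lists went from 0.376 to 0.218 and from −0.472 to −0.283.

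**Figure D2:**
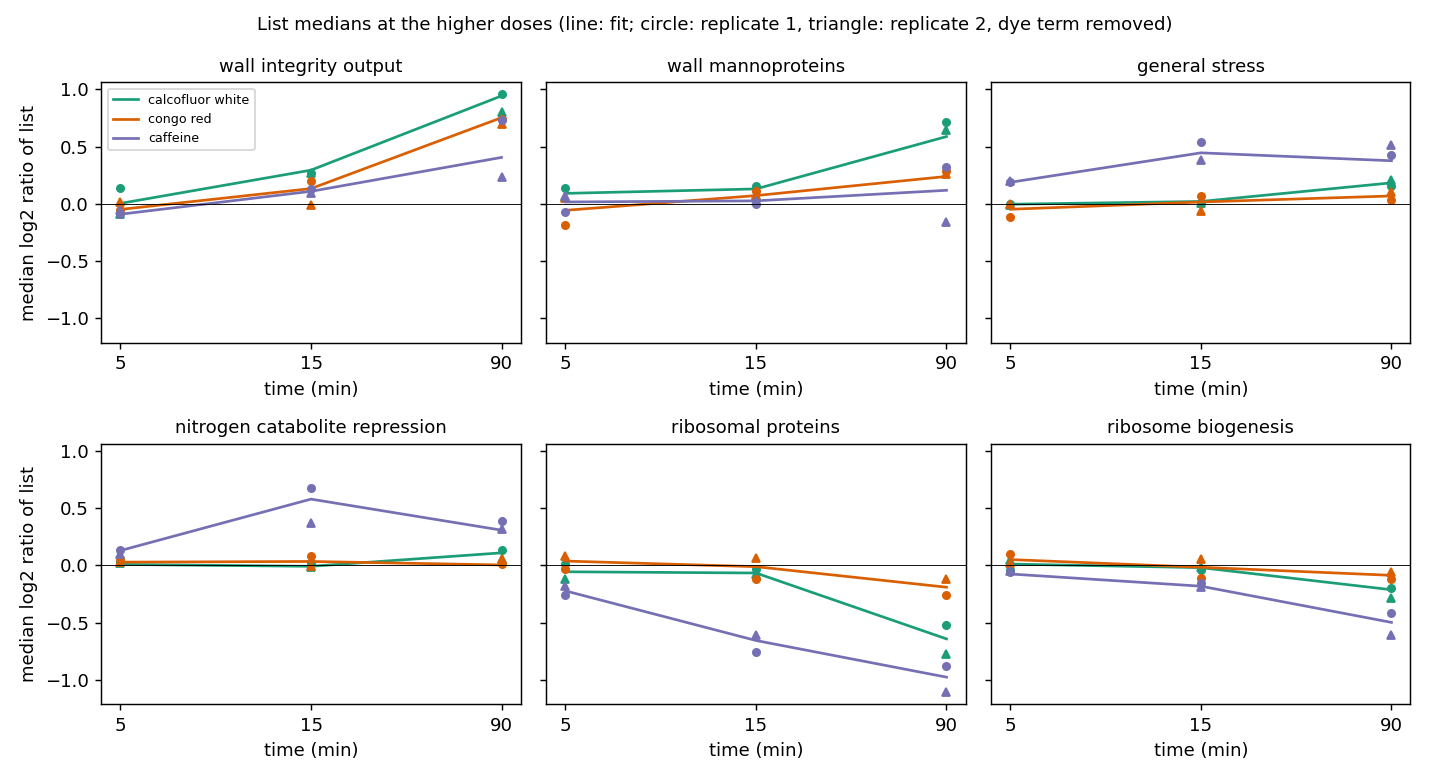
Median log2 ratio (y axis) of 6 gene lists at 5, 15 and 90 min (x axis, drawn with equal spacing) of the higher dose of each drug, with lines for the fit and symbols for each of the 2 arrays after the dye term was removed. At 90 min the wall integrity output list stands at 0.942 for calcofluor white and 0.752 for congo red, and the ribosomal protein list at −0.643 for calcofluor white and −0.977 for caffeine (−0.461 and −0.485 with scaled arrays, not drawn).

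At the lower dose of calcofluor white, averaged over the 3 times, PIR3 rose by 1.15 ± 0.126, CWP1 by 0.953 ± 0.143 and HSP12 by 0.913 ± 0.102, with YKE4 at 0.965 ± 0.22 and the glycerophosphodiesterase gene GDE1 at 1.01 ± 0.271. PHO3 fell by 0.754 ± 0.125 and the S-adenosylmethionine synthetase gene SAM1 by 0.56 ± 0.103, with PHO11 at −0.675 ± 0.193, ENT5 at −0.538 ± 0.143 and FAA4 at −0.513 ± 0.103. Limma called 257 genes, 121 higher and 136 lower. The count was 36 without the replicate block, 507 with only the arrays of this drug and 589 with array weights, and the split was 71 higher and 147 lower uncentred. Without 1 array the count was 127 and 77 (5 min replicates 1 and 2), 88 and 126 (15 min replicates 1 and 2) or 98 (90 min replicate 2). GDE1, YKE4, PHO11 and ENT5 did not pass without the replicate block. GDE1, YKE4 and ENT5 did not pass with scaled arrays, PHO11 and ENT5 with only the arrays of this drug, GDE1 and PHO11 with floored spots kept, PHO11 with well medians removed. ENT5 was lost with one value per spot. GDE1 did not pass without any 1 of the 6 arrays (0.936 to 1.08). PHO11, ENT5, YKE4 and FAA4 did not pass without 90 min replicate 2 (−0.534, −0.245, 0.914 and −0.451). PHO11 and ENT5 were also lost without either array of 5 or 15 min (PHO11 −0.633 to −0.718, ENT5 −0.502 to −0.575). YKE4 was lost without replicate 1 of 5 min (0.669) or 15 min (0.92), and FAA4 without replicate 2 of 5 min (−0.462). By time, 0 genes passed at 5 min (272 at an unadjusted p under 0.05; 19 with array weights, 8 with one value per spot, 1 with scaled arrays, and 11 and 13 without replicate 1 and 2). At 15 min 0 passed (111 unadjusted; 7 with array weights, and 9 and 3 without replicate 1 and 2). At 90 min 528 passed, 263 higher and 265 lower, with PIR3 at 2.59 ± 0.218, HSP12 at 2.66 ± 0.177 and PHO3 at −1.44 ± 0.217. The count at 90 min was 150 without the replicate block, 329 with scaled arrays, 838 with only the arrays of this drug, 256 without replicate 1 and 131 without replicate 2, and uncentred it split into 149 higher and 518 lower.

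At the lower dose of congo red, averaged over the 3 times, 9 genes rose and 0 fell, led by CWP1 (0.82 ± 0.144), PIR3 (0.812 ± 0.126), DNF2 (0.683 ± 0.134), the Sm protein gene SMX3 (0.679 ± 0.136) and CRG1 (0.482 ± 0.0923). DNF2 and SMX3 did not pass uncentred or with floored spots kept, DNF2 with well medians removed, SMX3 with only the arrays of this drug, and SMX3 and CRG1 with one value per spot. DNF2, SMX3 and CRG1 did not pass without the replicate block, where 2 genes were called, and the count was 3 uncentred, 23 with scaled arrays, 37 with array weights and 5 with floored spots kept. Without 1 array it was 1 and 2 (90 min replicates 1 and 2), 3 and 3 (15 min replicates 1 and 2) or 15 (5 min replicate 2). Each of these 5 genes was lost without some single array. CWP1 was lost at 0.759 to 0.851, PIR3 at 0.743 without 90 min replicate 2 and 0.763 without 15 min replicate 1, DNF2 at 0.607 to 0.721, SMX3 at 0.426 to 0.691 and CRG1 at 0.461 to 0.503. At 5 min limma called 0 genes (191 at an unadjusted p under 0.05; 7 with scaled arrays, and 14 and 24 without replicate 1 and 2). At 15 min it called 1, the DNA polymerase epsilon gene POL2 at −1.63 ± 0.271, named after its values were seen, with 0 uncentred, 0 with one value per spot, 0 over genes on all arrays, 5 with array weights, and 8 and 8 without replicate 1 and 2. At 90 min 36 genes rose and 1 fell, with PIR3 at 2.2 ± 0.219, CWP1 at 2.08 ± 0.249 and CRG1 at 1.16 ± 0.16, against 12 called without the replicate block, 93 with scaled arrays, 337 with array weights, and 9 and 16 without replicate 1 and 2.

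At 2 mM caffeine, averaged over the 3 times, the citrate synthase genes CIT2 (1.51 ± 0.114) and CIT1 (1.16 ± 0.101) and DIP5 (0.934 ± 0.113) rose most, followed by RPM2 (0.655 ± 0.144) and the mitochondrial ribosome gene MRPS5 (0.613 ± 0.0652). NOG2 fell by 0.501 ± 0.0931, SEF1 by 0.453 ± 0.0867 and TOM6 by 0.414 ± 0.0884. Limma called 29 genes, 26 higher and 3 lower. The count was 8 without the replicate block, 16 uncentred, 13 with scaled arrays, 2 with only the caffeine arrays and 3 with array weights. Without 1 array the count was 182 and 475 (5 min replicates 1 and 2), 56 and 11 (15 min replicates 1 and 2) or 14 (90 min replicate 1). RPM2, NOG2, SEF1 and TOM6 did not pass without the replicate block, and with only the caffeine arrays CIT2 and CIT1 alone of the 8 passed. With array weights CIT2, CIT1 and MRPS5 passed. With scaled arrays RPM2, NOG2 and TOM6 did not, with floored spots kept the same 3 did not (NOG2 −0.368). RPM2 and TOM6 did not uncentred or with one value per spot, and RPM2 did not with well medians removed. Without single arrays RPM2 (0.595 to 0.715), NOG2 (−0.447 and −0.473), SEF1 (−0.395 and −0.429) and TOM6 (−0.365 to −0.421) were lost. Of the 3 times averaged here, 15 min ran opposite to the others. Across genes 15 min correlated at −0.576 with 90 min and at −0.266 with 5 min, while 5 and 90 min correlated at 0.417. The values that involve 5 min hold for the labelled direction of its replicate 1, and were not computed with that sign turned. At 5 min, replicate 1 correlated at −0.375 across genes with replicate 1 of 2 mM at 15 min, which carries the same dye orientation. On replicate 2 well columns of the print plates held 20.2% of the variance against a median of 1.26% over arrays. With the sign of that replicate 1 turned, 9 genes were called and none of the 8 genes named here passed, with CIT2 at 0.805. The dyes are stated for these arrays, so the direction was kept. By time, 274 genes passed at 5 min (166 higher and 108 lower), 29 at 15 min (23 and 6) and 0 at 90 min, where 579 had an unadjusted p under 0.05. The 5 min count was 48 without the replicate block, 31 with scaled arrays, 0 with only the caffeine arrays, 0 with array weights, 650 with the sign turned, and 413 and 1478 without replicate 1 and 2. Uncentred, it split into 82 higher and 110 lower. The 15 min count was 11 without the replicate block, 0 with only the caffeine arrays, and 18 and 18 without replicate 1 and 2, with an uncentred split of 21 and 2. The 90 min count was 11 and 35 without replicate 1 and 2. CIT2 stood at 1.7 ± 0.197, 2.04 ± 0.197 and 0.774 ± 0.197 at 5, 15 and 90 min, the last not past the threshold. The 5 min CIT2 value and split of calls hold only for the labelled direction of replicate 1. No sign was turned at 90 min.

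Between doses, averaged over the times, caffeine was the drug with differences. MEP2 (2.72 at 20 mM and 0.719 at 2 mM, a difference of 2 ± 0.267), ARO9 (1.92 ± 0.192), the polyamine transporter gene TPO4 (1.91 ± 0.422), TFS1 (1.91 ± 0.375) and ARO10 (1.83 ± 0.105) were higher at 20 mM. NOG2 (−1.85 ± 0.131), FCF2 (−1.83 ± 0.261), the 18S rRNA acetyltransferase gene KRE33 (−1.68 ± 0.481), RPA135 (−1.66 ± 0.274) and NAN1 (−1.56 ± 0.256) were lower. Limma called 1232 genes, 551 higher and 681 lower at 20 mM. The count was 380 without the replicate block, 316 with scaled arrays, 496 with only the caffeine arrays, 543 with array weights and 815 without 20 mM 15 min replicate 1. TPO4, TFS1 and KRE33 did not pass with scaled arrays, TPO4 and KRE33 with only the caffeine arrays, and TPO4 with array weights. KRE33 stood at −0.0649 with the sign of 2 mM 5 min replicate 1 turned and was lost without 20 mM 90 min replicate 1 (−1.37), 20 mM 15 min replicate 1 (−1.5) or 2 mM 15 min replicate 2 (−1.55). At 90 min alone, a time chosen after the data were seen, 1238 genes differed (600 higher and 638 lower). The count was 502 without the replicate block, 150 with scaled arrays, 610 with only the caffeine arrays, 756 with array weights, 788 without 2 mM replicate 1 and 791 without 20 mM replicate 2.

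Between the doses of each dye limma called 0 genes, with 56 at an unadjusted p under 0.05 for calcofluor white and 42 for congo red. The smallest p values for calcofluor white belonged to MRPL27 (−0.54 ± 0.157), LGE1 (−0.51 ± 0.16), SAM1 (0.458 ± 0.146), LSM12 (−0.651 ± 0.211) and MDM30 (−0.264 ± 0.088), and for congo red to PAU6 (0.705 ± 0.153), POL2 (0.802 ± 0.221), SPC1 (−0.586 ± 0.194), SLZ1 (−0.633 ± 0.211) and RSC1 (−0.318 ± 0.11), none of which passed. Without 1 array the calcofluor white count was 65 (0.1 mg/ml 15 min replicate 2), 12 and 6 (0.02 mg/ml 90 and 5 min replicate 1), 3 (0.1 mg/ml 90 min replicate 1), or 1 (0.1 mg/ml 15 min replicate 1, 0.1 mg/ml 5 and 90 min replicate 2, and 0.02 mg/ml 15 and 90 min replicate 2). For congo red it was 4 (0.02 mg/ml 5 min replicate 2), 3 (either replicate 1 of 0.02 mg/ml at 5 and 15 min, or either 0.1 mg/ml array at 90 min), 2 (0.1 mg/ml 15 min or 0.02 mg/ml 90 min replicate 2), or 1 (either 0.1 mg/ml array at 5 min, or 0.1 mg/ml 15 min replicate 1). At 90 min alone the counts were again 0, with 104 and 92 genes at an unadjusted p under 0.05, though leaving out any array gave calls. For congo red at 90 min 1 gene was called uncentred and 1 with floored spots kept. These misses do not show that the doses acted alike. Some of these arrays have conflicting dose labels, among them calcofluor white 0.1 mg/ml 15 min replicate 2. Over genes on all arrays, all 32 splits of dose within time and dye orientation gave 0.

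Between 90 and 5 min of the higher dose, PIR3 and CWP1 were among the genes that differed for both dyes. For calcofluor white CSS3 (2.33 at 90 min and −0.252 at 5 min, a difference of 2.59 ± 0.402), PIR3 (2.44 ± 0.308), HSP12 (2.13 ± 0.25), CWP1 (2.05 ± 0.351) and NCE103 (1.97 ± 0.297) were higher at 90 min. PHO11 (−2.57 ± 0.473), RSA3 (−1.72 ± 0.473), ELC1 (−1.42 ± 0.34), FYV5 (−1.4 ± 0.246) and PHO3 (−1.32 ± 0.306) were lower. Limma called 207 genes, 107 higher and 100 lower. The count was 19 without the replicate block, 26 with scaled arrays (17 and 9), 137 with floored spots kept, 57 and 110 without 5 min replicate 1 and 2, and 62 without 90 min replicate 2. Uncentred, the split was 61 and 134, with the median gene at −0.1377. NCE103 and all 5 lower genes did not pass without the replicate block, and CWP1, RSA3, ELC1 and PHO3 did not pass with scaled arrays. RSA3 and ELC1 did not pass with only the arrays of this drug, RSA3 (−0.712) and PHO3 (−1.07) with floored spots kept, and FYV5 with one value per spot. All 5 lower genes were lost without single arrays. PHO11 was −1.32 without 90 min replicate 2, RSA3 was −0.384 without the same array and −1.64 and −1.8 without 5 min replicate 1 and 2, and ELC1 was −1.02 without 5 min replicate 1 and −0.954 without 90 min replicate 1. FYV5 was −1.18 and PHO3 −1.28 without 5 min replicate 1, FYV5 was −1.15 and PHO3 −1.19 without 90 min replicate 2, and PHO3 was −1.37 without 5 min replicate 2.

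For congo red PIR3 (2.57 ± 0.31), CWP1 (2.44 ± 0.353), DNF2 (1.76 ± 0.329), CRG1 (1.54 ± 0.226) and BUD7 (1.42 ± 0.272) were higher at 90 than at 5 min, and TAF3, of transcription factor TFIID, was lower (−0.977 ± 0.188). Limma called 15 genes, 14 higher and 1 lower. The count was 4 without the replicate block, 26 with scaled arrays, 27 with array weights and 7 without 5 min replicate 1. DNF2, BUD7 and TAF3 did not pass without the replicate block, BUD7 and TAF3 with only the arrays of this drug, and TAF3 uncentred, with scaled arrays, with floored spots kept or with well medians removed. CWP1 (2.02), DNF2 (1.49) and TAF3 (−0.778) were lost without 5 min replicate 1. BUD7 was lost without 5 min replicate 2 (0.894), DNF2 without 90 min replicate 1 (1.5), and BUD7 (1.27) and TAF3 (−0.746) without 90 min replicate 2. For caffeine at 20 mM, NQM1 (4.98 ± 0.627), DAL3 (4.65 ± 0.381), CPP3 (3.96 ± 0.457), TFS1 (3.8 ± 0.651) and HSP12 (3.78 ± 0.251) were higher at 90 min. NOG1 (−2.67 ± 0.462), DBP2 (−2.53 ± 0.538), RPA135 (−2.35 ± 0.476), RPO31 (−2.24 ± 0.31) and the 60S assembly gene RSA4 (−2.12 ± 0.456) were lower. Limma called 1701 genes, 876 higher and 825 lower. The count was 738 without the replicate block, 591 with scaled arrays (409 and 182), 752 with only the caffeine arrays, 1009 and 1069 without 5 min replicate 1 and 2, and 884 without 90 min replicate 2. The uncentred median gene stood at −0.173. TFS1, DBP2 and RPA135 did not pass with scaled arrays, and RSA4 was lost with only the caffeine arrays and without 5 min replicate 1 (−0.848).

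Caffeine at 20 mM was set against the mean of the 2 dyes at 0.1 mg/ml over the 3 times, at doses that cannot be matched. MEP2 was higher with caffeine (2.72 against −0.0399, a difference of 2.76 ± 0.23), as were TPO4 (2.62 ± 0.364), CIT2 (2.47 ± 0.138), ARO9 (2.42 ± 0.166) and ARO10 (2.11 ± 0.0904). NOG2 (−2.14 ± 0.113), FCF2 (−1.87 ± 0.225), CSI2 (−1.67 ± 0.101), SUI1 (−1.47 ± 0.11) and TYE7 (−1.43 ± 0.124) were lower. Limma called 1189 genes, 542 higher and 647 lower. The count was 455 without the replicate block and 439 with scaled arrays. The labels do not say whether the drugs were run together. Titles of the replicate 2 arrays carry another ending for calcofluor white than for congo red and caffeine, which the labels do not explain. The dye term is shared by all drugs, so a difference between such sets would not be removed. This bears on congo red against calcofluor white as well. At 90 min calcofluor white and caffeine shared 151 higher genes, where independent lists would share 73.8. They shared 324 lower genes, where independent lists would share 99.5. Of the calcofluor white calls, 14 higher and 23 lower genes were called the opposite way with caffeine. As for the dyes, the labels do not say whether untreated cultures were shared, so part of this excess may come from shared controls.

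**Figure D3:**
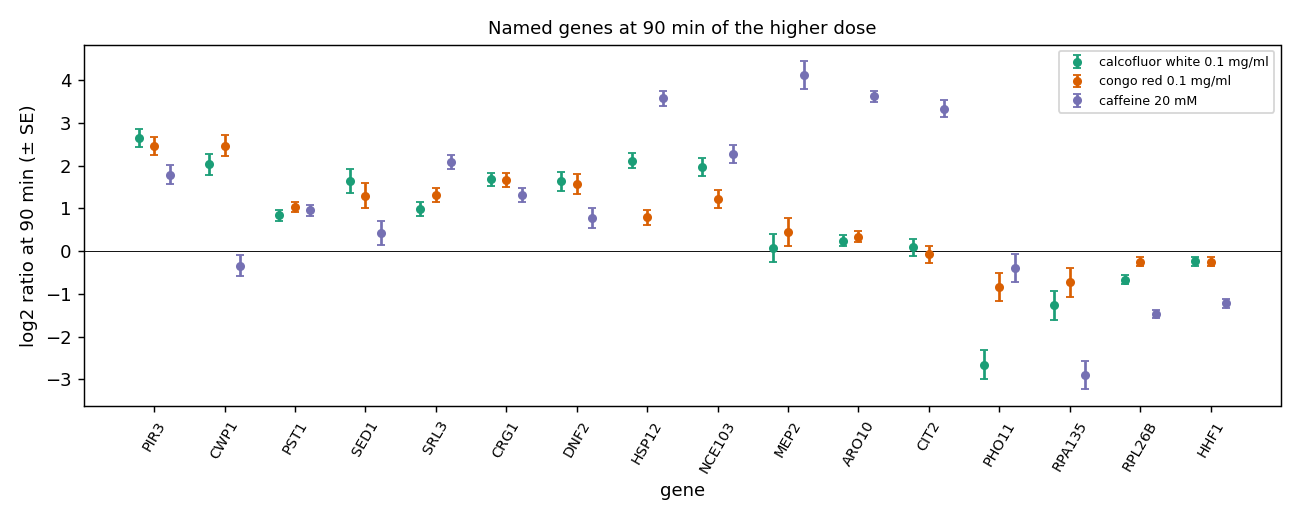
Log2 ratio ± SE (y axis) of 16 genes (x axis) after 90 min of the higher dose of each drug, from 2 arrays per drug. PIR3 stands at 2.65 with calcofluor white, 2.46 with congo red and 1.79 with caffeine, whereas MEP2 stands at 4.12 with caffeine and PHO11 at −2.66 with calcofluor white.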

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

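The tests of glycolysis genes and of the correlation between the 2 arrays of caffeine 2 mM at 5 min, and the intervals beside list medians, were chosen only after the result was seen. These intervals come from resampling the genes of a list and hold no spread between the 2 arrays.

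A difference between conditions was found by a test of the difference itself for the doses of caffeine, where 1232 genes differed, with MEP2 (2.00), ARO9 (1.92), TPO4 (1.91), TFS1 (1.91) and ARO10 (1.83) higher and NOG2 (−1.85), FCF2 (−1.83), KRE33 (−1.68), RPA135 (−1.66) and NAN1 (−1.56) lower at 20 mM. Between 90 and 5 min of calcofluor white 207 genes differed, with CSS3 (2.59), PIR3 (2.44), HSP12 (2.13), CWP1 (2.05), NCE103 (1.97), PHO11 (−2.57), RSA3 (−1.72), ELC1 (−1.42), FYV5 (−1.40) and PHO3 (−1.32). For congo red 15 differed, with PIR3 (2.57), CWP1 (2.44), DNF2 (1.76), CRG1 (1.54), BUD7 (1.42) and TAF3 (−0.98). For caffeine 1701 differed, with NQM1 (4.98), DAL3 (4.65), CPP3 (3.96), TFS1 (3.80), HSP12 (3.78), NOG1 (−2.67), DBP2 (−2.53), RPA135 (−2.35), RPO31 (−2.24) and RSA4 (−2.12). Between caffeine and the 2 dyes 1189 differed, with MEP2 (2.76), TPO4 (2.62), CIT2 (2.47), ARO9 (2.42), ARO10 (2.11), NOG2 (−2.14), FCF2 (−1.87), CSI2 (−1.67), SUI1 (−1.47) and TYE7 (−1.43). A signal in spots without a gene name was found at 90 min of caffeine at 20 mM, where 274 of 1511 tested spots passed the threshold, 136 higher and 138 lower.

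Regrouping the arrays was used to weigh chance. No other split called as many genes as the real one for low-dose calcofluor white (261 genes, and 159 in the highest of the other splits), low-dose congo red (10 and 8), the doses of caffeine (1029 and 750) and caffeine against the dyes (1010 and 852). The real split is itself 1 of the 32, 32, 32 and 100 splits compared. With so few splits, and no adjustment over the several tests, chance is less likely there but not excluded. For low-dose congo red the margin was small. For low-dose caffeine 11 of 32 sign changes gave as many genes as the real 27, so that count was not set apart from chance. The highest of them called 933, and the reason for this was not tested. For the doses of each dye and for congo red against calcofluor white all 32 of 32 splits gave 0, as the real ones did.

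The first pattern weighed was the 274 genes called for caffeine 2 mM at 5 min. Removing the medians of well rows and columns left 240 calls, which argues against well rows and columns as the whole cause. Plate and place on the slide were not modelled. Across genes the 2 arrays correlated at −0.0118 once the dye term was removed, so the calls may come from values of single arrays that the other array does not share. An early effect of caffeine was not tested apart from that and stays open.

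The second pattern was that caffeine 2 mM at 90 min ran opposite to 20 mM at 15 min across genes (−0.481). The correlation was −0.498 with well medians removed, and −0.231 and −0.346 across replicate numbers, which argues against print position and against arrays of 1 replicate number processed together. A rebound of ribosome synthesis genes could not be settled, since the lower of the 2 medians of the ribosome biogenesis list was −0.00468 (−0.0913 to 0.0852) and the other 0.00684. That interval was added after the medians were seen and moved the reading from excluded to open. At 2 mM and 90 min the ribosomal protein list, outside that test, stood at 0.217 (0.354 and 0.0791 on replicates 1 and 2). RNA polymerases I and III stood at 0.108 (0.167 and 0.00189). These go with a rebound, but glycolysis genes stood at 0.217 too (0.416 and 0.014). The rise was not particular to ribosome synthesis and lay mostly on replicate 1. An inverted or mislabelled replicate 1 was not tested, and this and a rebound stay open.

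The third pattern was the fall of ribosomal protein genes at 90 min of calcofluor white at 0.1 mg/ml (median −0.643) and of caffeine at 20 mM (−0.977, and −0.485 with scaled arrays). A lower ratio for all very abundant transcripts would need glycolysis genes to reach at least −0.322 and −0.488, which is the midpoint between 0 and each ribosomal protein median. For calcofluor white their median was −0.15 (−0.2 to −0.0132 when genes are resampled). On replicates 1 and 2 it was 0.0131 and −0.23 after the dye term was removed, both outside that interval. Both lie nearer 0 than −0.322, which argues against that explanation as the whole cause for the genes measured. The list lacks TDH3 and ENO1, the number of arrays limits this reading, and a part of the fall may still come from it. For caffeine the median was −0.255 (−0.551 to −0.134). That interval spans the midpoint, so there the explanation cannot be told apart from a response of ribosome synthesis to the drug. Such a response was not tested by itself and stays open for both drugs. The reading changed after these values were seen. With a bound nearer 0 than the midpoint, both drugs were first read as excluded from the medians alone, and as open once the intervals and, for caffeine, the genes of the list test were used. Calcofluor white was read as excluded again once the bound was moved to the midpoint.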

How the results depend on the processing

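Floored spots kept, well medians removed, a turned sign, 90 min alone and low doses at single times were chosen only after the result was seen. Counts run calcofluor white (CFW), congo red (CR), caffeine, with H and L for higher and lower dose. Dropping the block keeps estimates but adds dye variance to the residual. Other causes are untested. A lone array is assumed to vary like the other conditions.

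Without the replicate block the counts were CFW H 15 min 0, 90 min 231, CR H 5 min 0, 90 min 16, caffeine H 5 min 5, 15 min 667, 90 min 1389, L means 36, 2 and 8. They were caffeine doses 380, 90 against 5 min 19, 4 and 738, caffeine against dyes 455. Also moved were L CFW 90 min 150, L CR 90 min 12, L caffeine 5 min 48 and 15 min 11, CR against CFW at 90 min 0 and caffeine doses at 90 min 502. Uncentred they were CR H 5 min 0, L CR mean 3, L caffeine mean 16, L CR 15 min 0, CR against CFW at 90 min 24 and CR doses at 90 min 1. Scaled they were CFW H 15 min 30, 90 min 352, CR H 5 min 8, caffeine H 190, 561 and 899. Scaling gave L CR mean 23, L caffeine mean 13, caffeine doses 316, 90 against 5 min 26, 26 and 591, caffeine against dyes 439. It gave L CFW 5 min 1 and 90 min 329, L CR 5 min 7 and 90 min 93, L caffeine 5 min 31, CR against CFW at 90 min 0 and caffeine doses at 90 min 150. With genes on all arrays they were CFW H 15 min 42, CR H 5 min 0 and L CR 15 min 0. With only the arrays of the drugs compared they were CFW H 15 min 0, CR H 5 min 0, 90 min 133, caffeine H 5 min 0, 15 min 797. They gave L CFW mean 507, L caffeine mean 2, caffeine doses 496. They also gave 90 against 5 min of caffeine 752, L CFW 90 min 838, L caffeine 5 min 0 and 15 min 0, CR against CFW at 90 min 47 and caffeine doses at 90 min 610. With array weights they were CFW H 5 min 5, 15 min 24, caffeine H 5 min 563, 90 min 1541. Weights gave L means 589, 37 and 3, caffeine doses 543, 90 against 5 min of CR 27. Weights also gave L CFW 5 min 19, 15 min 7, L CR 15 min 5, 90 min 337, L caffeine 5 min 0, CR against CFW at 90 min 8 and caffeine doses at 90 min 756. With floored spots kept they were CFW H 15 min 2, CR H 5 min 0, L CR mean 5, 90 against 5 min of CFW 137, CR against CFW at 90 min 5 and CR doses at 90 min 1. With well medians removed they were CFW H 15 min 25, CR H 5 min 0 and CR against CFW at 90 min 9. With the sign turned, L caffeine was 9 (mean) and 650 (5 min). CR against CFW was 15 at 90 min only. Per spot, CR H 5 min was 0, L CFW 5 min 8 and L CR 15 min 0. Of the 51 list calls an estimated correlation kept 7. Fry called 82, but kept 40 of the 51 and lost 11. Lost were 8 without the block, 3 uncentred, 1 scaled, 8 with genes on all arrays, 2 with floored spots kept and 0 with well medians removed.

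Leaving out 1 array gave these lowest and highest counts: CFW H 5 to 28, 14 to 115 and 240 to 399 at 5, 15 and 90 min. For CR H they were 7 to 7, 4 to 5 and 27 to 51, caffeine H 24 to 74, 412 to 1245 and 1187 to 1975. The L means gave 77 to 177, 1 to 15 and 11 to 475. For doses they were 0 to 65, 0 to 4 and 815 to 1712, 90 against 5 min 57 to 169, 7 to 20 and 884 to 1649. Between drugs, CR against CFW gave 0 to 73, caffeine against dyes 880 to 1275. At single times, L CFW gave 11 to 13, 3 to 9 and 131 to 256, L CR 14 to 24, 8 to 8 and 9 to 16, L caffeine 413 to 1478, 18 to 18 and 11 to 35. At 90 min CR against CFW gave 4 to 54 and doses 4 to 34, 2 to 7 and 788 to 1271. List calls were 36 without replicate 1 (19 of the 51 lost) and 57 without replicate 2 (10 lost).

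Signs reversed for these genes, given without replicate 1 and then without replicate 2. In CFW H they were OST3 (−0.107, 2.58), PDC1 (−0.375, 0.0113) and PGI1 (−0.286, 0.0667) at 5 min, RPL40A (0.0098, −4.32), RPS9B (0.0301, −3.17), CWP1 (1.18, −0.0776) and CRZ1 (1.2, −0.252) at 15 min, and ARP6 (−2.47, 0.0182) at 90 min. In CR H they were PIR3 (−0.026, 0.669) and BOR1 (−2.15, 0.0303) at 15 min, and STE3 (0.0389, −0.275) and NOP19 (−1.74, 0.145) at 90 min. Of 332 named gene values, 239 past the threshold, those that kept direction and side were 262 without the block, 320 uncentred, 290 scaled, 304 with weights, 332 with a robust prior, 316 with floored spots and 321 with well medians removed, and 1030 of 1218 with 1 array left out. The 2 arrays per condition limit all of these counts.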

Other observations

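The tests described here were planned, except that the setting with floored spots kept and the choice of which list results to place here were chosen only after the result was seen.

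Histone genes were lower at 90 min of calcofluor white at 0.1 mg/ml, where of 9 measured genes 0 rose, 5 fell and 4 did not pass (6 lower adjusted over the list alone), with HHT2 at −0.741 ± 0.135 and HTB2 at −0.76 ± 0.147 (camera adjusted p = 0.000536, and adjusted p = 0.272 with an estimated correlation). Both genes did not pass without the replicate block or without replicate 2 (HHT2 −0.411, HTB2 −0.537). The call of the list was lost without the replicate block (adjusted p = 0.163). At 15 min of caffeine at 20 mM 0 rose, 4 fell and 5 did not pass (4 lower adjusted over the list alone), with HTB1 at −0.864 ± 0.161 (camera adjusted p = 0.0315, and adjusted p = 0.543 with an estimated correlation). HTB1 was lost without the replicate block, with scaled arrays and without replicate 1 (−0.695). The list was lost without the replicate block (adjusted p = 0.44), uncentred (0.0525), over genes on all arrays (0.0702) and without replicate 1 (0.0677). At 90 min 0 rose, 8 fell and 1 did not pass (9 lower adjusted over the list alone), with a median of −1.13 (−0.574 with scaled arrays) and HHF1 at −1.22 ± 0.107 (camera adjusted p = 3.29e-06, and adjusted p = 0.136 with an estimated correlation). At 90 min of congo red at 0.1 mg/ml 0 rose, 0 fell and 9 did not pass (3 lower adjusted over the list alone), with a median of −0.24 (camera adjusted p = 0.000684, and adjusted p = 0.272 with an estimated correlation). That list was lost without the replicate block (adjusted p = 0.228) and without replicate 1 (0.102).

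Genes of alpha cells were lower at 90 min of caffeine at 20 mM, where of 4 genes 0 rose, 3 fell and 1 did not pass (4 lower adjusted over the list alone), with a median of −0.659 (−0.346 with scaled arrays), the pheromone genes MF(ALPHA)1 and MF(ALPHA)2 among those that fell (camera adjusted p = 0.0376, and adjusted p = 0.447 with an estimated correlation). The list was lost without the replicate block (adjusted p = 0.058), uncentred (0.0525) and without replicate 1 (0.0677) or 2 (0.0844). At 90 min of congo red at 0.1 mg/ml 0 rose, 1 fell and 3 did not pass (2 lower adjusted over the list alone), with a median of −0.331, MF(ALPHA)2 being the gene that fell (camera adjusted p = 0.00688, and adjusted p = 0.272 with an estimated correlation). The gene was lost without the replicate block, uncentred, with floored spots kept and without either replicate, and the list without replicate 1 (adjusted p = 0.248). Of 19 genes of purine and one-carbon synthesis at 90 min of calcofluor white at 0.1 mg/ml, 0 rose, 7 fell and 12 did not pass (9 lower adjusted over the list alone), with ADE12 at −0.609 ± 0.118, lost without replicate 2 (−0.529) (camera adjusted p = 0.000153, and adjusted p = 0.272 with an estimated correlation).

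At 90 min of congo red at 0.1 mg/ml 1 of 32 proteasome genes rose, 0 fell and 31 did not pass (2 higher adjusted over the list alone), PRE8 at 0.458 ± 0.0984 (camera adjusted p = 0.00264, and adjusted p = 0.313 with an estimated correlation). Of 18 unfolded protein response genes 1 rose, 0 fell and 17 did not pass (2 higher adjusted over the list alone), FPR2 at 0.615 ± 0.124 (camera adjusted p = 0.0241, and adjusted p = 0.136 with an estimated correlation). PRE8 and FPR2 were lost without the replicate block and without replicate 1 (0.435 and 0.691) or 2 (0.48 and 0.54). Of 14 calcineurin targets 1 rose, 0 fell and 13 did not pass (2 higher adjusted over the list alone), KRE6 at 0.663 ± 0.131, lost without the replicate block and without replicate 1 (0.489) (camera adjusted p = 0.0305, and adjusted p = 0.48 with an estimated correlation). KRE6 was also counted above among the chitin and glucan synthesis genes. Of 105 ribosome biogenesis genes 0 rose, 0 fell and 105 did not pass, also when adjusted over the list alone (median −0.0882, −0.0509 uncentred, camera adjusted p = 0.0174, and adjusted p = 0.586 with an estimated correlation). Without replicate 1 the unfolded protein response, calcineurin and ribosome biogenesis lists were lost (adjusted p = 0.158, 0.421 and 0.522), the last 2 also with fry (0.129 and 0.262).

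Further lists called at 5 or 15 min with 0 genes past the threshold over all genes were as follows, beside the wall integrity output genes at 15 min of both dyes and the ribosomal proteins at 5 min of caffeine at 20 mM, given above. At 5 min of calcofluor white at 0.1 mg/ml they were ribosomal proteins (122 genes, median −0.0573, −0.0165 uncentred, camera adjusted p = 0.0114, and adjusted p = 0.812 with an estimated correlation) and glycolysis (14 genes, −0.108, −0.0688 uncentred, camera adjusted p = 0.0388, and adjusted p = 0.545 with an estimated correlation), with 0 adjusted over the list alone. At 15 min they were mannoproteins (28 genes, 0.13, 1 lower adjusted over the list alone, camera adjusted p = 0.0346, and adjusted p = 0.615 with an estimated correlation) and ribosomal proteins (117 genes, −0.0679, −0.0111 uncentred, 2 lower adjusted over the list alone, camera adjusted p = 0.019, and adjusted p = 0.814 with an estimated correlation). They were also calcineurin targets (14 genes, 0.177, 0 adjusted over the list alone, camera adjusted p = 0.00451, and adjusted p = 0.297 with an estimated correlation) and G2/M genes (11 genes, −0.108, −0.0405 uncentred, 1 lower adjusted over the list alone, camera adjusted p = 0.0216, and adjusted p = 0.157 with an estimated correlation). At 15 min of congo red at 0.1 mg/ml it was mannoproteins (28 genes, 0.0719, 0 adjusted over the list alone, camera adjusted p = 0.0114, and adjusted p = 0.586 with an estimated correlation). At 5 min of caffeine at 20 mM they were general stress genes (39 genes, 0.181, 0 adjusted over the list alone, camera adjusted p = 0.0154, and adjusted p = 0.203 with an estimated correlation) and calcineurin targets (14 genes, −0.26, 0 adjusted over the list alone, camera adjusted p = 0.00942, and adjusted p = 0.355 with an estimated correlation). Each of these 9 calls was lost with an estimated correlation and without at least 1 replicate. Fry lost all but the G2/M list and both caffeine lists. The 2 ribosomal protein calls and that of glycolysis were also lost without the replicate block, and much of the ribosomal protein medians came from centring.

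Of the 38 lists, 19 had no call in any of the 9 conditions. The smallest camera adjusted p of each was 0.249 for components of the wall integrity pathway, 0.0973 for wall remodelling enzymes, 0.0912 for heat shock chaperones, 0.0919 for amino acid synthesis, 0.0775 for methionine and sulfur genes, and 0.0763 for the retrograde response. It was 0.18 for glucose-repressed carbon metabolism, 0.18 for multidrug resistance, 0.404 for oxidative stress, 0.102 for the iron regulon, and 0.31 for ergosterol synthesis. It was 0.108 for autophagy, 0.249 for TOR and Ras-cAMP components, 0.499 for pheromone response, 0.451 for DNA damage, 0.39 for G1/S, 0.453 for M/G1 daughter-cell, 0.21 for a-cell and 0.0975 for meiosis and sporulation genes. A miss does not show that these genes did not respond.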
